A study of Homo sapiens with 204 samples.

How the data were processed

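Gene expression was measured with Affymetrix exon arrays in subcutaneous and visceral adipose tissue of 51 subjects, of whom 11 were non-pregnant, 25 were pregnant and not in labor, and 15 were in labor. Each subject gave 1 array per region, and each of the 102 arrays stands in the deposited data at 2 levels, which makes 204 sample records. The gene-level table holds 18708 transcript clusters and the exon-level data hold 284258 probe sets. All columns of both tables were used, and each was assigned to a sample by its name.

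The values the authors deposited are log2 expression values. They were made with RMA (robust multi-array average) in R 3.2.2 against genome build hg19, per the submitters' processing notes. RMA corrects the background, brings the arrays to a common distribution and summarises the probes of a feature on the log2 scale, so small differences in overall signal between arrays had been removed before deposit and summarised values of weak features are compressed. The probe file used for the summaries is not given in the sources used here. Array medians of the gene-level table lay between 7.01 and 7.25 log2 units. Arrays have no read depth, and their number limits the precision.

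Gene names came from the array annotation given with the tables. Of the transcript clusters, 14733 had 1 gene symbol, 2875 had several and 1100 had no symbol there. Of the probe sets, 261182 had 1 symbol, 9155 several and 13921 none. Symbols were updated through an NCBI gene table of assembly GRCh38.p14, in which 14731 of the 1-symbol clusters were found. That table's build differs from the submitters', so it served for names alone and no genome coordinates are printed. Clusters and probe sets with several symbols were tested but never named.

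The labels state that regions are paired within a subject and groups are unpaired, and the fits follow them. Differences between regions were tested with limma 3.58.1 in R 4.3.3 on each subject's visceral minus subcutaneous log2 value, with 1 mean per group. Differences between groups were tested within each region. All 3 groups shared the estimate of the spread. The 9 gene-level comparisons were the region in each group, pregnancy and labor in each region, and the interaction of pregnancy and of labor with region. Pregnancy means pregnant not in labor minus non-pregnant, and labor means in labor minus pregnant not in labor. The groups hold different subjects, so rises and falls with pregnancy or labor are differences between subjects. The labels used here give group, region and subject number and no batch. Other differences between the groups therefore cannot be told apart from pregnancy or labor. A cluster was called at a Benjamini-Hochberg adjusted p under 0.05 over all clusters, with empirical Bayes variances and no minimum fold. The pairing comes from the subject number in the labels. The residuals of a subject's pair of arrays, after removing group means, correlated with a median of 0.158, against -0.00 for arrays of different subjects, and 30 of 51 pairs were above 0.1.

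The comparisons, the tests, the gene lists, the rule for named genes and the other settings to be run were fixed before the data were examined. Gene lists were tested with limma's camera at a preset correlation of 0.01 and again with a correlation estimated per list, and adjusted within each comparison. Of the 45 lists, 44 had at least 5 measured members. Where a gene had several clusters, the brightest stood for it. For each comparison the named genes are the 10 with the largest positive and the 10 with the largest negative difference among called 1-symbol clusters, or the 5 with the smallest p where none was called, and up to 4 members of each list described, taken by smallest p. XIST, TSIX and Y-linked genes were never named.

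Splicing was tested on the exon-level table. The splicing index of a probe set is its log2 value minus the median of its gene's kept probe sets in the same array. Probe sets under the 25th percentile of mean log2, genes with fewer than 5 kept probe sets and genes whose median probe set was under the median of all probe sets were left out, which left 147153 probe sets of 9349 genes. A gene was called when at least 1 probe set reached an adjusted p under 0.05 and a difference of at least 0.5, and the 5 called genes with the smallest p are named. The index measures unequal change within a gene and does not by itself separate splicing from probe sets that respond unequally.

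The other settings were no pairing, a random subject effect, a fit on the compared groups alone, brighter clusters alone, arrays centred on their median, trended and robust variances and a minimum 1.5-fold difference. For splicing they were no minimum difference, the gene-level table as gene level, brighter probe sets, no pairing and limma's diffSplice. For lists the alternative was the estimated correlation. After the data were seen, fits were added without 5 pairs whose arrays carried marker levels of the other region, without the subjects of 3 arrays with a median correlation under 0.93 to the other arrays, without both sets, and with limma's array weights. The 5 pairs were found from the means of 16 mesothelial markers and 4 HOXC genes, so leaving them out selects on regional markers and the region counts without them are not independent evidence. No array was left out of the results as described.

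The fits were tested on simulated data. In the simulated region comparison of the pregnant group not in labor, over 18708 clusters, 96 percent of 100 clusters changed by 0.5 and 100 percent of 100 changed by 1 were recovered, with 10 calls among 18508 unchanged clusters. In the simulated pregnancy comparison of subcutaneous arrays, over the same number of clusters, 93 percent and 100 percent were recovered, with 7 calls among 18508 unchanged. In simulated splicing by region in the pregnant group not in labor, 98.5 percent of 200 shifted probe sets were recovered over 36000. Among the other probe sets 16 were called, and a change of whole genes gave 0 calls. The index subtracts the gene's median and the whole-gene change was equal in all its probe sets, so these 0 calls were fixed beforehand. They say nothing about probe sets that respond unequally. Of 30 simulated lists of unchanged genes, 0 were called. The simulated clusters varied independently of each other, and no outlying arrays or pairs at odds with their region were simulated. The false calls counted here therefore do not give the error rate in the real data. Figures were drawn with matplotlib 3.10.9.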

Results

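Adipose tissue stores triglyceride in adipocytes and also holds vessels, immune cells, fibroblasts and, in visceral depots, the mesothelium that covers the peritoneal surface. Expression was measured on exon arrays in subcutaneous and visceral adipose tissue of 51 subjects, 11 non-pregnant, 25 pregnant and not in labor and 15 in labor, with 1 array per subject and region. The series addressed how gene expression and splicing differed with pregnancy, labor and adipose region. Values below are log2 expression as deposited, and differences between them are log2 differences with standard errors (SE) unless a fold is given. In 5 of the 51 pairs at least 1 array carried mesothelial and HOXC levels nearer the median of the other region, which concerned 5 subcutaneous and 4 visceral arrays. Of the 40 pregnant subjects 36 were left without these pairs. Leaving them out moved the mean regional difference of mesothelial markers most in labor, from 1.39 to 2.08. It moved from 1.90 to 2.08 in the pregnant group not in labor and from 1.27 to 1.56 in the non-pregnant group. A further 3 arrays, all from non-pregnant subcutaneous tissue, had a median correlation with the other arrays under 0.93, where the median over arrays was 0.957. All arrays were kept.

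The first comparison asked how visceral and subcutaneous tissue of the same subject differed. In the 25 pregnant subjects not in labor, ITLN1, which encodes the secreted lectin omentin, had the largest regional difference, with 10.14 ± 1.17 (SD, n = 25) in visceral and 5.70 ± 1.24 (SD, n = 25) in subcutaneous arrays. The difference was 4.44 ± 0.54 (SE), or 21.7-fold, and was higher in 24 of 25 pairs (limma adjusted p = 3.61e-08). The tight junction gene CLDN1 was 17.3-fold higher in visceral tissue, the lipoxygenase gene ALOX15 7.51-fold, the signalling regulator RGS4 6.33-fold and the protease inhibitor TFPI2 6.08-fold, each in 24 of 25 pairs. The zinc transporter SLC39A8, the integrin ITGB8, the steroid dehydrogenase HSD17B6 and the surface proteins LRRN4 and FLRT3 were between 5.74-fold and 5.90-fold higher, also in 24 of 25 pairs. Subcutaneous tissue had the higher level of VEGFD, a growth factor for lymphatic vessels, with a visceral difference of -2.42 ± 0.29 (limma adjusted p = 2.43e-08, 24 of 25 pairs). It also had more of the proteolipid gene NNAT (-1.97 ± 0.26), the microfibril gene MFAP5 (-1.64 ± 0.24), APOB (-1.56 ± 0.18) and the endothelial adhesion gene SELE (-1.54 ± 0.34). PI16, a gene of adventitial fibroblasts, HOXC10, the peroxisomal transporter ABCD2, the acyltransferase GLYAT and the transcription factor SIM1 differed by -1.53 to -1.44. In all, limma called 4294 clusters in this group, 2163 higher and 2131 lower in visceral tissue.

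ITLN1 and CLDN1 had the largest visceral increases in the other groups too. In the 11 non-pregnant subjects ITLN1 was 11.6-fold higher in visceral tissue (3.53 ± 0.81, limma adjusted p = 0.0163, 10 of 11 pairs), CLDN1 8.30-fold, the terminal complement gene C7 5.03-fold, RGS4 4.12-fold and the immunoglobulin joining chain JCHAIN 3.91-fold. ALOX15, TFPI2, complement factor B (CFB), the zinc finger gene BNC1 and SLC39A8 were 3.22-fold to 3.91-fold higher. NNAT was lower by a difference of -1.50 ± 0.40 (limma adjusted p = 0.0275, 10 of 11 pairs). So were the aldolase gene ALDOC (-1.26 ± 0.26), the peptide hormone gene SPX (-1.25 ± 0.30), MYOC (-1.11 ± 0.27), NRN1 (-1.05 ± 0.27) and HOXC10 (2.01-fold lower). Genes of triglyceride turnover were among the 10 largest negative differences too, with the monoglyceride lipase MGLL (-0.98 ± 0.22), the triglyceride synthase DGAT2 (-0.96 ± 0.25) and the antilipolytic adrenoceptor ADRA2A (-0.95 ± 0.22), next to ITIH5 (-0.90 ± 0.25). Of these 20 genes only C7, ALDOC and MGLL still passed without the subjects of the 3 low-correlation arrays, and ITLN1 stood at 3.66 with a limma adjusted p of 0.0551. In the 15 subjects in labor ITLN1 was 8.30-fold higher (3.05 ± 0.69, limma adjusted p = 0.0022, 13 of 15 pairs) and CLDN1 6.95-fold. They were followed by ITGB8, the secreted Wnt inhibitor DKK1 (4.58-fold), SLC39A8, HSD17B6, RGS4, CFB, the prolactin receptor PRLR (3.79-fold, 14 of 15 pairs) and MMRN1 (3.78-fold). NNAT, VEGFD, MFAP5, the calcium-binding CASQ2, APOB, the Wnt antagonist SFRP4, GLYAT, SIM1, PI16 and ABCD2 differed by -1.43 to -1.18 there. limma called 700 clusters in the non-pregnant group (327 higher and 373 lower) and 2714 in labor (1531 higher and 1183 lower). In all 3 groups 423 were called in a common direction, 174 higher and 249 lower in visceral tissue.

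Mesothelial markers rose together in visceral tissue. Of the 16 measured, 16 were called higher in the pregnant group not in labor, 14 in labor and 6 in the non-pregnant group, against 16, 15 and 15 adjusted over the list alone. Their mean differences were 1.90, 1.39 and 1.27 (limma camera adjusted p = 8.71e-22, 6.46e-13 and 1.28e-13; adjusted p = 0.0651, 0.215 and 0.198 with an estimated correlation). Without the 5 pairs at odds with their region label the means were 2.08, 2.08 and 1.56 (limma camera adjusted p = 0.0016, 0.0043 and 0.0038 with an estimated correlation). Those pairs were found in part from these markers, so this is not independent evidence. With all pairs, the mesothelial transcription factor WT1 differed by 2.14 ± 0.25, 1.52 ± 0.32 and 1.56 ± 0.38 in these groups. The keratin gene KRT8 differed by 2.02 ± 0.24, 1.51 ± 0.32 and 1.39 ± 0.37. Transcription factors of regional patterning went both ways. In the pregnant group not in labor 7 of 22 were called higher and 11 lower, with HOXC10 at -1.49 ± 0.18, HOXC9 at -0.96 ± 0.11 and TWIST1 at -0.75 ± 0.10 (7 and 11 adjusted over the list alone). In the non-pregnant group 3 were called higher, among them NR2F1 at 0.93 ± 0.24, and 6 lower (6 and 12 adjusted over the list alone). In labor 5 were called higher and 11 lower, with TBX5 at -0.76 ± 0.16 (5 and 11 adjusted over the list alone), and camera passed in this group alone (limma camera adjusted p = 0.0267, adjusted p = 0.588 with an estimated correlation).

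Adipocyte genes were lower in visceral tissue. Of 18 measured genes of adipocyte identity, 17 were called lower in the pregnant group not in labor, 16 in labor and 6 in the non-pregnant group, and none higher (17, 17 and 12 lower adjusted over the list alone). The mean differences were -0.64, -0.56 and -0.41 (limma camera adjusted p = 8.59e-17, 2.24e-12 and 1.43e-06; adjusted p = 0.0651, 0.215 and 0.416 with an estimated correlation). The retinol carrier RBP4 differed by -1.13 ± 0.12 in the pregnant group not in labor, in 25 of 25 pairs, and by -0.74 ± 0.19 in the non-pregnant group. Lipoprotein lipase (LPL) differed by -0.86 ± 0.12 and the adipogenic receptor PPARG by -0.72 ± 0.10 in the pregnant group not in labor. In labor the hormone-sensitive lipase gene LIPE differed by -0.70 ± 0.14, CEBPA by -0.56 ± 0.12 and the insulin-regulated glucose transporter SLC2A4 by -0.65 ± 0.14. Among 16 genes of lipolysis and its control, 14, 9 and 5 were called lower in the pregnant group not in labor, in labor and in the non-pregnant group (15, 14 and 11 adjusted over the list alone). The limma camera adjusted p was 6.41e-11, 4.94e-08 and 1.90e-05, against adjusted p = 0.0651, 0.215 and 0.416 with an estimated correlation. The antilipolytic phosphodiesterase PDE3B differed by -0.86 ± 0.13 and -0.77 ± 0.17 in these pregnant groups. Of 21 genes of lipogenesis and triglyceride synthesis 15 were lower and 1 higher in the pregnant group not in labor and 12 lower in labor (15 and 1, and 13 and 1 adjusted over the list alone; limma camera adjusted p = 1.40e-07 and 1.46e-06; adjusted p = 0.392 and 0.403 with an estimated correlation). In the non-pregnant group 7 were lower. They included DGAT1 at -0.65 ± 0.13 and the pyruvate carboxylase gene PC at -0.49 ± 0.13 (11 adjusted over the list alone; limma camera adjusted p = 3.88e-05; adjusted p = 0.427 with an estimated correlation). The lists overlap and are not separate evidence. Adipocyte identity shares LIPE, PNPLA2, PLIN1, AQP7 and FABP4 with lipolysis, and GPAM and THRSP with lipogenesis.

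Lymphatic and complement genes were higher in visceral tissue. Of 7 measured lymphatic endothelial markers, 6 were called higher in the pregnant group not in labor and 5 in each other group. Adjusted over the list alone they were 6, 6 and 5 in the pregnant group not in labor, the non-pregnant group and labor, with mean differences of 1.10, 0.88 and 0.85 in that order. The limma camera adjusted p was 1.53e-09, 3.89e-09 and 5.63e-06, against adjusted p = 0.0565, 0.0355 and 0.215 with an estimated correlation. The chemokine CCL21 differed by 2.27 ± 0.26, TFF3 by 1.30 ± 0.16, RELN by 1.05 ± 0.11 and the lymphatic regulator PROX1 by 0.70 ± 0.09 in the pregnant group not in labor. Of 17 complement genes, 8 were called higher in the non-pregnant group (11 higher and 2 lower adjusted over the list alone; limma camera adjusted p = 5.49e-11; adjusted p = 0.0355 with an estimated correlation). Among them were C7 at 2.33 ± 0.35, C1QB at 0.76 ± 0.18 and C3 at 0.74 ± 0.18. Pregnant subjects not in labor had 10 complement genes called higher and 2 lower. Examples were CFB at 2.23 ± 0.29, CFI at 1.67 ± 0.24 and the adipocyte product CFD at -0.52 ± 0.08 (11 and 3 adjusted over the list alone; limma camera adjusted p = 0.0034; adjusted p = 0.467 with an estimated correlation). Macrophage markers were called higher in the non-pregnant group for 7 of 19 genes, including CD163 at 0.93 ± 0.23 and AIF1 at 0.51 ± 0.11 (12 adjusted over the list alone; limma camera adjusted p = 9.01e-12; adjusted p = 0.198 with an estimated correlation), and for 0 without the subjects of the 3 low-correlation arrays, where the mean was 0.39 against 0.44. The list did not pass in the pregnant group not in labor, with 5 higher and 1 lower (6 and 1 adjusted over the list alone; limma camera adjusted p = 0.0760), or in labor, with 0 called by limma (0 adjusted over the list alone; limma camera adjusted p = 0.146). Of 20 T and NK cell markers, 18 were called higher in the pregnant group not in labor and 9 in labor (19 and 15 adjusted over the list alone; limma camera adjusted p = 1.32e-10 and 3.61e-08; adjusted p = 0.305 and 0.403 with an estimated correlation). They included the cytotoxic genes PRF1 at 0.40 ± 0.07 and NKG7 at 0.71 ± 0.14 in the former and GZMK at 1.07 ± 0.28 in the latter. None was called in the non-pregnant group (6 adjusted over the list alone; limma camera adjusted p = 2.46e-06; adjusted p = 0.416 with an estimated correlation).

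Lists of matrix, interferon response and unfolded protein response genes passed in some of the groups, and ribosomal proteins in all 3. Of 37 extracellular matrix genes, 19 were called lower and 3 higher in visceral tissue of the pregnant group not in labor. The basement membrane collagens were lower, COL4A1 at -0.81 ± 0.12 and COL4A2 at -0.70 ± 0.10, while LAMB1 stood at 0.93 ± 0.11 and TIMP1 at 1.05 ± 0.15 (23 and 3 adjusted over the list alone; limma camera adjusted p = 3.40e-06; adjusted p = 0.415 with an estimated correlation). This list did not pass in the non-pregnant group or in labor (limma camera adjusted p = 0.0923 and 0.112), but passed in both without the 5 pairs at odds with their region label (limma camera adjusted p = 0.0142 and 6.13e-06; adjusted p = 0.685 and 0.277 with an estimated correlation). It also passed in the non-pregnant group without the subjects of the 3 low-correlation arrays (limma camera adjusted p = 3.56e-04; adjusted p = 0.498 with an estimated correlation). Of 32 interferon response genes, 10 were called higher in the pregnant group not in labor and 11 in labor (12 and 17 adjusted over the list alone; limma camera adjusted p = 5.52e-05 and 1.14e-08; adjusted p = 0.593 and 0.403 with an estimated correlation). IRF9 stood at 0.39 ± 0.08 and 0.41 ± 0.11, and the list did not pass in the non-pregnant group (limma camera adjusted p = 0.227). Of 19 genes of the unfolded protein response, which raises the folding capacity of the endoplasmic reticulum, 11 were called higher and 1 lower in labor. Those higher included the chaperones HYOU1 at 0.69 ± 0.12 and HSPA5 at 0.76 ± 0.14 and the transcription factor XBP1 at 0.56 ± 0.11 (13 and 1 adjusted over the list alone; limma camera adjusted p = 7.61e-09; adjusted p = 0.142 with an estimated correlation). Without labor 9 were called higher in the pregnant group, led by CHAC1 at 2.01 ± 0.25 (10 higher and 1 lower adjusted over the list alone; limma camera adjusted p = 8.65e-04; adjusted p = 0.392 with an estimated correlation). Non-pregnant subjects had 1 called lower and none higher, and the list did not pass (limma camera adjusted p = 0.0662). Ribosomal protein genes were called higher for 6 of 27 in the non-pregnant group, with RPS6 at 0.34 ± 0.09 and RPL26 at 0.33 ± 0.09 (23 adjusted over the list alone; limma camera adjusted p = 3.11e-18; adjusted p = 0.198 with an estimated correlation). They were called higher for 11 in the pregnant group not in labor and 1 in labor (12 and 1 adjusted over the list alone; limma camera adjusted p = 1.52e-05 and 7.49e-04; adjusted p = 0.593 and 0.677 with an estimated correlation).

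**Figure D1:**
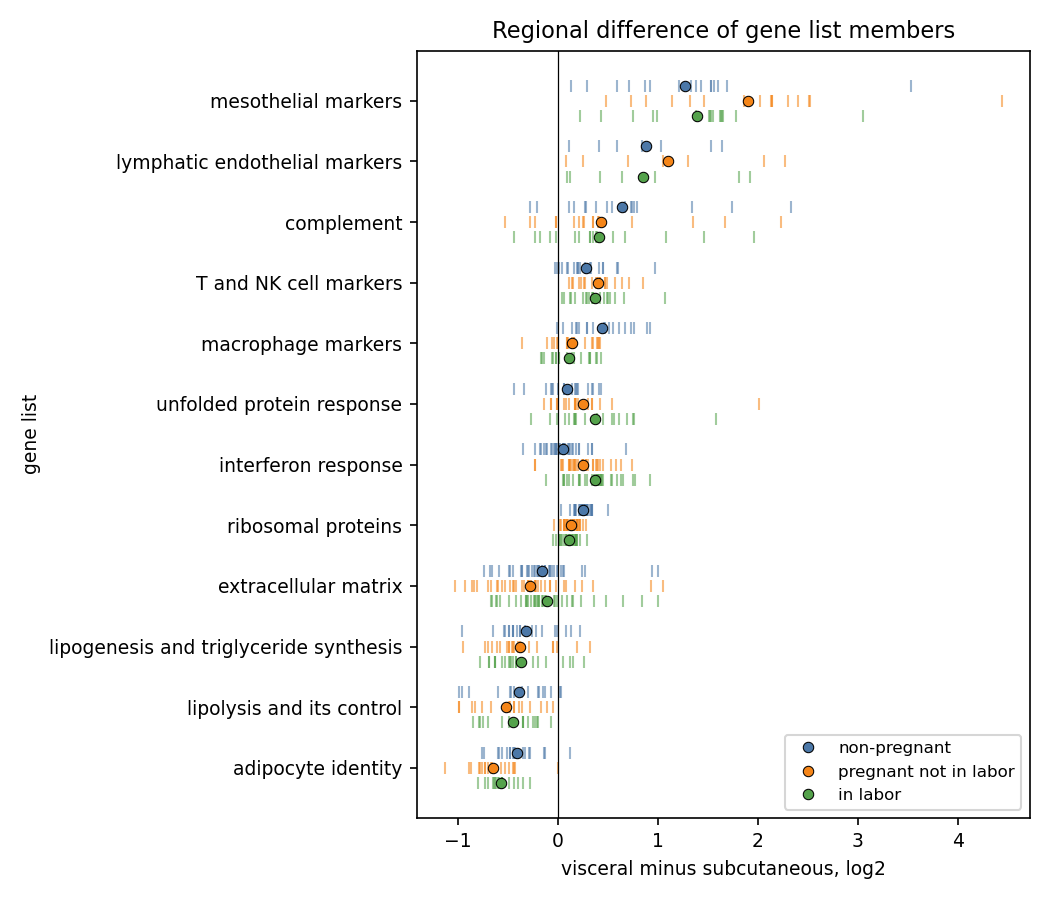
Regional difference of gene list members. The horizontal axis is the visceral minus subcutaneous difference in log2 units, each tick is 1 measured gene of the list and each dot is the list's mean, in colour for the non-pregnant, pregnant not in labor and in labor groups. Mesothelial markers lie to the right with means of 1.27, 1.90 and 1.39, and adipocyte identity genes to the left with means of -0.41, -0.64 and -0.56.

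The regional counts moved with the fit, and so did some sizes. In labor ITLN1, CLDN1 and VEGFD differed by 4.68, 4.24 and -2.15 once the pairs at odds with their region label were left out. Those pairs were found from regional markers, so these sizes are not independent evidence. Without the 5 pairs at odds with their region label 2886 clusters were called in the non-pregnant group, 5251 in the pregnant group not in labor and 4563 in labor, and without the subjects of the 3 low-correlation arrays the non-pregnant count was 72. Of the non-pregnant list members called, the mesothelial markers fell from 6 to 0, complement genes from 8 to 1, lymphatic markers from 5 to 0, adipocyte identity genes from 6 to 1 and ribosomal protein genes from 6 to 0 with those subjects left out, in limma. Their mean differences there were 1.43, 0.58, 0.89, -0.53 and 0.22, so calls were lost more than size. Likewise lipogenesis genes fell from 7 to 1 (mean -0.48), lipolysis genes from 5 to 1 (mean -0.49) and patterning factors from 3 higher and 6 lower to 0 (limma). Complement and lymphatic markers lost their pass with an estimated correlation there (limma camera adjusted p = 1.87e-06 and 9.05e-08; adjusted p = 0.102 and 0.0893 with an estimated correlation). A fit on the non-pregnant group alone called 0 clusters with limma (2969 at an unadjusted p under 0.05). The difference in region between groups was tested by interaction, and limma called 0 clusters for pregnancy by region (814 at an unadjusted p under 0.05) and 0 for labor by region (499 at an unadjusted p under 0.05). The genes with the smallest p for pregnancy by region, none of which passed, were led by the immediate early gene IER2 with an interaction of 0.67 ± 0.15. After it came SPON1 with -0.85 ± 0.21, LYVE1 with -0.76 ± 0.19, FUT1 with 0.38 ± 0.10 and NREP with -0.89 ± 0.23 (limma adjusted p = 0.798 for IER2 and 0.845 for the others). For labor by region they were the sialic acid synthase NANS with 0.37 ± 0.10, the mitochondrial import gene TIMM17A with 0.51 ± 0.13 and AAGAB with 0.23 ± 0.06, followed by the secretory coat gene SEC24D with 0.53 ± 0.15 and the disulfide isomerase PDIA5 with 0.43 ± 0.12 (limma adjusted p = 0.972). Without the 5 pairs, 9 clusters were called for pregnancy by region, and IER2, SPON1 and LYVE1 passed with 0.76, -1.04 and -0.89 (limma adjusted p = 0.0129, 0.0129 and 0.0344).

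The next comparison asked which genes differed in subcutaneous tissue between pregnant subjects not in labor and non-pregnant subjects. The terminal complement genes C7 and C6 rose 2.46-fold and 2.40-fold, C7 from 8.60 ± 1.21 (SD, n = 11) to 9.89 ± 0.55 (SD, n = 25), with a difference of 1.30 ± 0.28 (limma adjusted p = 0.0032). The difference for C6 was 1.26 ± 0.23 (limma adjusted p = 7.66e-04). Genes of resident macrophages rose with them, among them the complement receptor VSIG4 (2.10-fold), MS4A4A (2.01-fold), the anaphylatoxin receptor C3AR1 (1.96-fold), the hyaluronan receptor LYVE1 (1.89-fold) and the complement starter C1QA (1.79-fold). The red cell carbonic anhydrase CA1 (2.45-fold), the kinase scaffold CAB39L (1.97-fold) and the adhesion receptor ADGRG2 (1.85-fold) were also among the 10 largest increases. EGFL6, which encodes a secreted matrix ligand, was the largest decrease with -1.52 ± 0.32 (2.87-fold lower, limma adjusted p = 0.0029). The purine enzyme PNP (2.27-fold), the matrix proteases ADAMTS4 (2.12-fold) and ADAMTS9 (1.99-fold), and the bradykinin receptor BDKRB1 (1.85-fold) were lower. The same held for the AP-1 subunit FOSL1 (1.81-fold), the cytokine receptor TNFRSF12A (1.80-fold) and hexokinase HK2 (1.79-fold), and for the paralogous olfactory receptor genes OR52N5 (1.93-fold) and OR52N1 (1.84-fold), whose probes were not checked for binding each other's transcript. limma called 1492 clusters, 841 higher and 651 lower.

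Of 19 macrophage markers 15 rose and none fell (16 adjusted over the list alone), with a mean of 0.54 (limma camera adjusted p = 5.70e-14; adjusted p = 0.209 with an estimated correlation). Examples were VSIG4 at 1.07 ± 0.18, the growth factor receptor CSF1R at 0.66 ± 0.12, C1QC at 0.78 ± 0.15 and F13A1 at 0.80 ± 0.15. Of 17 complement genes 8 rose, including the C1q chains that macrophages make and that the macrophage list also holds, with a mean of 0.47 (10 adjusted over the list alone; limma camera adjusted p = 1.22e-08; adjusted p = 0.183 with an estimated correlation). Of 37 extracellular matrix genes 8 rose. Examples were the membrane protease MMP14 at 0.59 ± 0.09, the collagen COL14A1 at 0.63 ± 0.17, versican (VCAN) at 0.74 ± 0.22 and the gelatinase MMP2 at 0.55 ± 0.16 (10 adjusted over the list alone; limma camera adjusted p = 2.98e-07; adjusted p = 0.439 with an estimated correlation). Fibroblast and preadipocyte markers had a mean of 0.25 over 17 members with 0 called by limma (3 adjusted over the list alone; limma camera adjusted p = 0.0056; adjusted p = 0.746 with an estimated correlation). Ribosomal protein genes rose for 11 of 27, with RPL27 at 0.27 ± 0.06 (24 adjusted over the list alone; limma camera adjusted p = 5.91e-14; adjusted p = 0.436 with an estimated correlation). Of 18 endothelial markers 3 fell. They were the endothelial transcription factor SOX17 at -0.66 ± 0.11, the tight junction gene CLDN5 at -0.37 ± 0.09 and ROBO4 at -0.22 ± 0.07 (7 adjusted over the list alone; limma camera adjusted p = 0.0322; adjusted p = 0.915 with an estimated correlation). Mesothelial markers had a mean of -0.08 and 0 of 16 called (0 adjusted over the list alone; limma camera adjusted p = 0.958).

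Without the subjects of the 3 low-correlation arrays, which all belong to the non-pregnant subcutaneous group, 125 clusters were called, 44 higher and 81 lower, and 124 of them were among the 1492. C6, VSIG4, LYVE1, ADGRG2, EGFL6, OR52N5, OR52N1, FOSL1, TNFRSF12A and HK2 still passed there, with limma adjusted p from 0.0016 for HK2 to 0.0324 for TNFRSF12A, and the other 10 did not, C7 for instance at 1.09 with a limma adjusted p of 0.0773. Of the list members above, 5 macrophage markers, 2 complement genes, 1 extracellular matrix gene and 1 ribosomal protein gene were still called higher. Of the endothelial markers 1 was still called lower. The means of these lists there were 0.52, 0.39, 0.20, 0.19 and -0.28. For them camera passed at the preset correlation alone (limma camera adjusted p at most 1.30e-05, adjusted p = 0.109 to 0.403 with an estimated correlation). Fibroblast and preadipocyte markers did not pass there (mean 0.17, limma camera adjusted p = 0.0796, adjusted p = 0.8015 with an estimated correlation).

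In visceral tissue the same comparison gave fewer calls. DKK1, a secreted inhibitor of Wnt signalling, rose 4.20-fold in pregnancy, from 8.11 ± 1.31 (SD, n = 11) to 10.18 ± 1.35 (SD, n = 25), a difference of 2.07 ± 0.44 (limma adjusted p = 0.0155). CHAC1, a glutathione-degrading enzyme of the unfolded protein response, rose 2.73-fold, CA1 2.08-fold, ADGRG2 2.06-fold, the hedgehog release protein DISP1 2.04-fold, the AP-1 subunit FOS 1.94-fold and the heme synthesis enzyme ALAS2 1.94-fold. The proteoglycan SPOCK1, the glycosyltransferase GALNT15 and the estrogen-responsive gene GREB1 rose by 0.80 ± 0.21, 0.79 ± 0.18 and 0.78 ± 0.18. Among the 10 largest decreases were heme oxygenase HMOX1 at -0.92 ± 0.19 (limma adjusted p = 0.0125) and the glutathione synthesis subunit GCLM at -0.78 ± 0.15 (limma adjusted p = 0.0077). The other 8 were the cysteine dioxygenase CDO1 (-0.75 ± 0.15), the glycosyltransferase B4GALT6 (-0.78 ± 0.15), the transcription factor NFATC2 (-0.78 ± 0.19), FOSL1 (-0.77 ± 0.20), S100B (-0.76 ± 0.19), HIVEP2 (-0.74 ± 0.17), OR52N1 (-0.94 ± 0.23) and OR52N5 (-0.89 ± 0.23). limma called 159 clusters, 89 higher and 70 lower.

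Of 24 immediate early genes 3 rose and 1 fell. They were IER2 at 0.72 ± 0.13, FOS at 0.96 ± 0.19, KLF2 at 0.41 ± 0.10 and FOSL1 at -0.77 ± 0.20 (9 and 1 adjusted over the list alone; limma camera adjusted p = 1.22e-04; adjusted p = 0.697 with an estimated correlation). Of 9 erythroid markers CA1 and ALAS2 rose (5 higher and 1 lower adjusted over the list alone; limma camera adjusted p = 0.0074; adjusted p = 0.697 with an estimated correlation). Of 16 growth hormone and prolactin signalling genes 1 rose, the growth factor binding protein IGFBP4 at 0.31 ± 0.06. PRLR differed by 1.81 ± 0.55 without passing (3 higher and 1 lower adjusted over the list alone; limma camera adjusted p = 0.0280; adjusted p = 0.697 with an estimated correlation). Of 11 heat shock genes BAG3 fell, at -0.46 ± 0.12 (3 adjusted over the list alone; limma camera adjusted p = 0.0014; adjusted p = 0.697 with an estimated correlation). Several lists moved with no member called over all clusters. Mesothelial markers had a mean of 0.56 (limma camera adjusted p = 3.45e-05), macrophage markers 0.25 with 4 adjusted over the list alone (limma camera adjusted p = 1.22e-04) and adipocyte identity genes -0.26 with 3 lower adjusted over the list alone (limma camera adjusted p = 0.0014), each at adjusted p = 0.697 with an estimated correlation.

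Between regions 97 clusters were called for pregnancy in a common direction, 41 higher and 56 lower, and 0 in opposite directions in limma. Over all clusters the pregnancy differences of the regions correlated with a Pearson r of 0.633, a value across genes, which are not independent replicates, from arrays of the same subjects. ADGRG2, CA1, SPOCK1, HK2, FOSL1, HMOX1, GCLM, B4GALT6, NFATC2, CDO1, OR52N1 and OR52N5 were named genes called in both. Among the named genes EGFL6 and CHAC1 differed most between the regions, by 1.70 and 1.57 in the interaction, which did not pass (limma adjusted p = 0.845 for each). Without the subjects of the 3 low-correlation arrays 2 clusters were called in visceral tissue, among them ADGRG2 at 1.08 (limma adjusted p = 0.0068). DKK1 at 2.05, CHAC1 at 1.28, FOS at 0.92 and HMOX1 at -0.54 were not called there. The 3 arrays are subcutaneous, so the visceral arrays left out with them were not themselves under the correlation limit. Leaving out 3 other non-pregnant subjects was not tried in visceral tissue. In a fit on the compared groups alone 79 clusters were called.

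**Figure D2:**
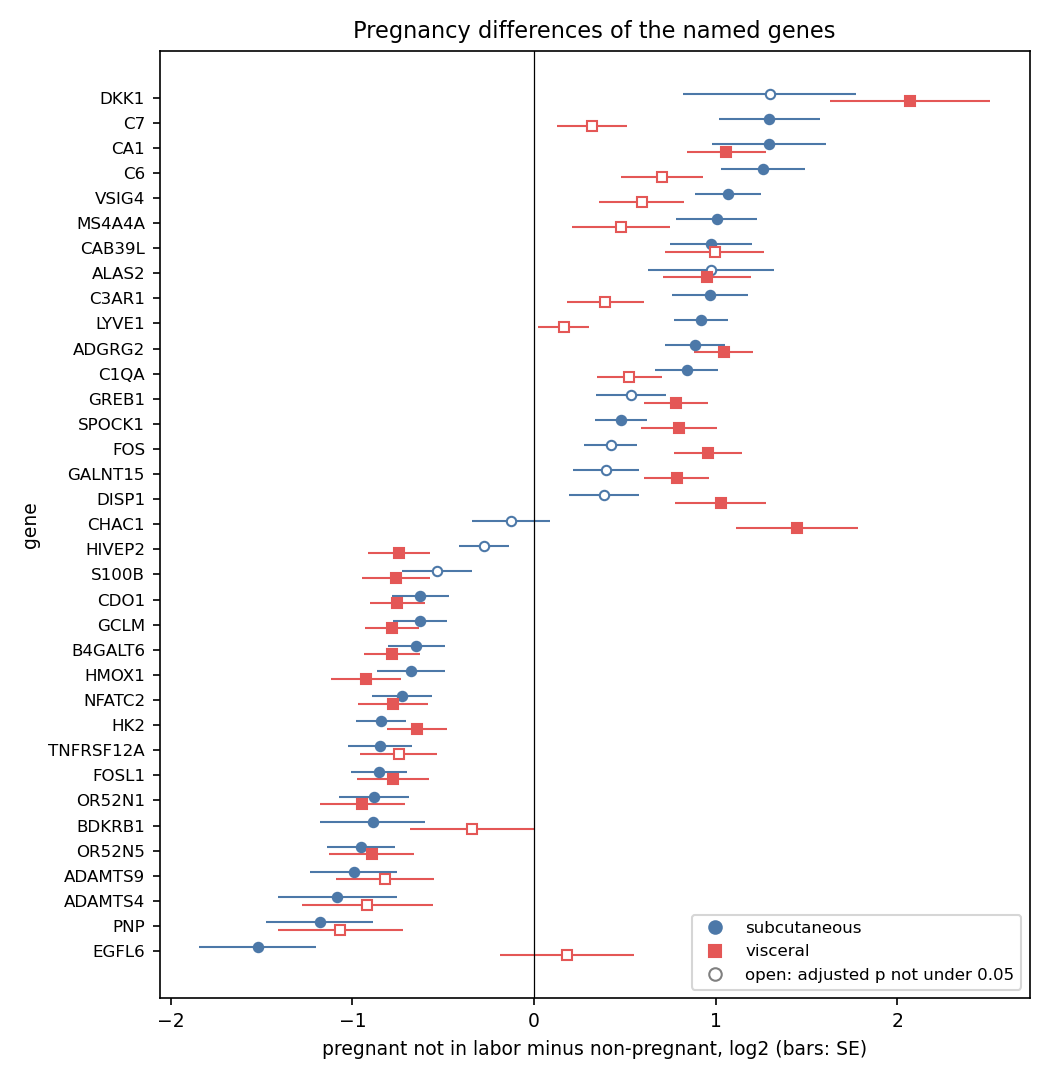
Pregnancy differences of the named genes. The horizontal axis is the difference of pregnant subjects not in labor minus non-pregnant subjects in log2 units, with circles for subcutaneous and squares for visceral tissue, bars for 1 SE and open symbols where the adjusted p was not under 0.05. ADGRG2 and CA1 rose in both regions, with 0.89 and 1.05 for ADGRG2, whereas EGFL6 was at -1.52 in subcutaneous and 0.18 in visceral tissue.

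Labor was compared with pregnancy without labor in each region. In visceral tissue no gene passed, and the genes with the smallest p were led by FAM98A at 0.42 ± 0.09. The next 4 were the disulfide isomerase PDIA6 at 0.44 ± 0.10, the hexosamine enzyme GFPT1 at 0.42 ± 0.09, the translocon subunit SEC61A1 at 0.28 ± 0.06 and the signal recognition receptor SRPRB at 0.57 ± 0.13 (limma adjusted p = 0.158 for each, n = 25 and 15). limma called 0 clusters, with 1834 at an unadjusted p under 0.05. Among 19 genes of the unfolded protein response the mean was 0.15, with 0 members called over all clusters and 9 adjusted over the list alone (limma camera adjusted p = 2.81e-06; adjusted p = 0.269 with an estimated correlation). Its members included PDIA6, MANF at 0.22 ± 0.06, HYOU1 at 0.32 ± 0.10 and HSPA5 at 0.38 ± 0.12. Oxidative phosphorylation genes had a mean of 0.12 over 37 members, with COX7A2 at 0.40 ± 0.12 and NDUFB3 at 0.36 ± 0.11 (0 called over all clusters, 2 adjusted over the list alone; limma camera adjusted p = 5.41e-08; adjusted p = 0.809 with an estimated correlation). Adipocyte identity and lipogenesis genes had means of 0.13 and 0.12, with 0 called by limma in each (0 adjusted over the list alone; limma camera adjusted p = 0.0350 for each; adjusted p = 0.848 with an estimated correlation). Neither passed without the 5 pairs (limma camera adjusted p = 0.0574 and 0.370). Heat shock genes had a mean of 0.20 over 11 members, with the mitochondrial chaperones HSPD1 at 0.34 ± 0.11 and HSPE1 at 0.26 ± 0.10 (0 called over all clusters, 1 adjusted over the list alone; limma camera adjusted p = 2.88e-05; adjusted p = 0.751 with an estimated correlation). With limma's array weights 172 clusters were called.

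In subcutaneous tissue no gene passed for labor either. The smallest p belonged to the glycosidase MANEA at 0.36 ± 0.09 and the phosphate transporter SLC20A2 at -0.23 ± 0.06. Next came ARHGAP19 at -0.32 ± 0.08, the RNA-binding EWSR1 at -0.22 ± 0.06 and AKAP8 at -0.15 ± 0.04 (limma adjusted p = 1.0000 for each). limma called 0 clusters, with 659 at an unadjusted p under 0.05 and 0 under every alternative run. Mesothelial markers had a mean of 0.44 over 16 members with 0 called (0 adjusted over the list alone; limma camera adjusted p = 5.31e-12; adjusted p = 0.654 with an estimated correlation), with ITLN1 at 1.10 ± 0.53. The mean was 0.11 without the 5 pairs at odds with their region label. Endothelial markers had a mean of -0.16 over 18 members with 0 called (0 adjusted over the list alone; limma camera adjusted p = 4.71e-08; adjusted p = 0.654 with an estimated correlation), with PECAM1 at -0.34 ± 0.13.

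**Figure D3:**
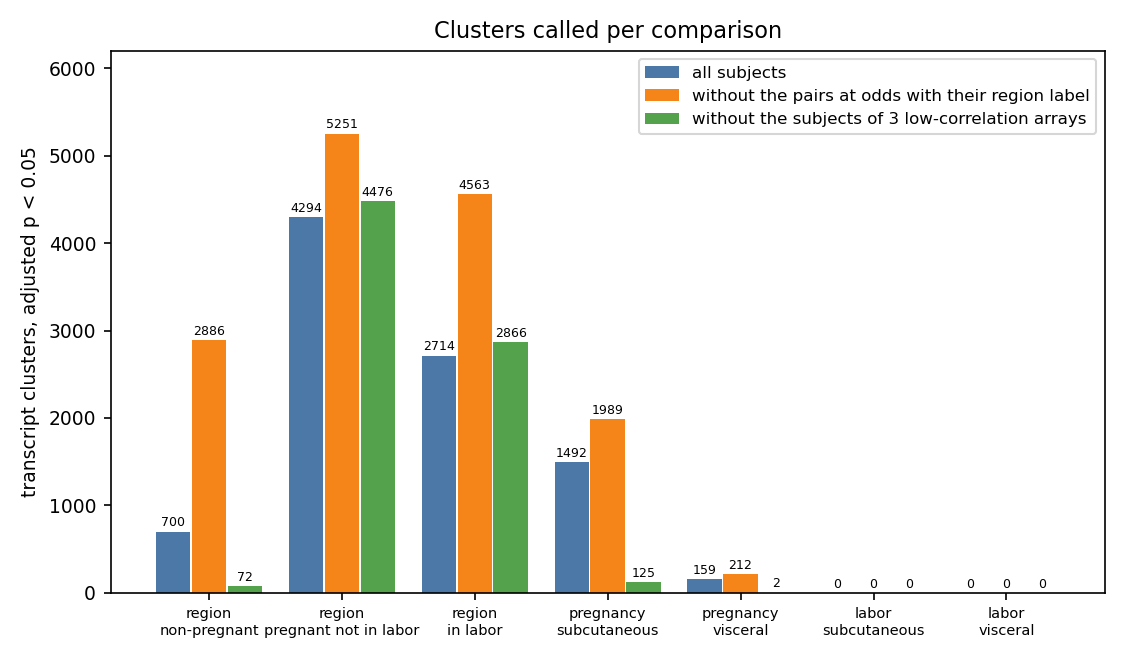
Clusters called per comparison. Bars give the number of transcript clusters called by limma over 18708, for all subjects, without the 5 pairs at odds with their region label and without the subjects of the 3 low-correlation arrays. The pregnancy bars in subcutaneous tissue stand at 1492, 1989 and 125.

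Splicing was compared through the splicing index, the level of a probe set relative to its gene. In the pregnant group not in labor a probe set of BNC1 had an index of -0.32 ± 0.56 (SD, n = 25) in visceral and 2.63 ± 0.72 (SD, n = 25) in subcutaneous arrays. The difference was -2.95 ± 0.32 (limma adjusted p = 4.25e-08, 24 of 25 pairs). KRT18 (-0.91 ± 0.10), the claudin CLDN15 (1.33 ± 0.14), LRRN4 (-1.001 ± 0.11) and the stomach patterning factor BARX1 (1.99 ± 0.22) followed, each in 24 of 25 pairs. In the non-pregnant group they were mesothelin (MSLN, 2.74 ± 0.44), C7 (-1.23 ± 0.21), the retinaldehyde dehydrogenase ALDH1A3 (-1.10 ± 0.19), KRT18 (1.36 ± 0.24) and ALOX15 (1.51 ± 0.27), each in 10 of 11 pairs. The KRT18 values of the 2 groups come from different probe sets, so they do not show a reversal. In the pregnant group not in labor 13 of the 16 KRT18 probe sets were called. In labor they were the iron-binding MELTF (-1.06 ± 0.17), the kinase ALPK3 (0.53 ± 0.08), ALDH1A3 (-1.48 ± 0.24), the folate enzyme MTHFD1L (1.00 ± 0.17) and PDLIM4 (0.62 ± 0.11), in 14 or 15 of 15 pairs. limma called 799 genes in the pregnant group not in labor (2050 probe sets), 475 in labor (948) and 81 in the non-pregnant group (151). In all, 66 probe sets of 34 genes were called in all 3 groups in a common direction. In the pregnant group not in labor BNC1, KRT18 and LRRN4 were higher in visceral tissue at gene level, by 2.40, 2.14 and 2.52. Their named probe sets thus went against their gene. CLDN15 and BARX1 were higher by 1.28 and 0.71, and their named probe sets went with their gene. The index does not separate splicing from probe sets that respond unequally.

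For pregnancy, limma called 73 genes in subcutaneous tissue (112 probe sets) and 8 in visceral tissue (23). ADGRG2 led in subcutaneous tissue, where a probe set rose relative to its gene by 1.32 ± 0.17 (limma adjusted p = 7.74e-05, n = 11 and 25) and 14 of its 26 probe sets were called. EPB41L4B (0.71 ± 0.11), ADAMTSL4 (0.63 ± 0.10), MMP14 (-1.11 ± 0.17) and SPON1 (-0.75 ± 0.12) followed. In visceral tissue they were the angiogenic ligand PROK1 (1.33 ± 0.16, limma adjusted p = 3.33e-06), ADGRG2 (0.84 ± 0.11), the nuclear receptor NR4A3 (2.09 ± 0.32), SCHIP1 (-0.72 ± 0.12) and GREB1 (-0.99 ± 0.17). For labor, limma called 1 gene in subcutaneous tissue, the mitochondrial GHITM (-0.52 ± 0.09, limma adjusted p = 0.0328). In visceral tissue limma called 0 (10336 probe sets at an unadjusted p under 0.05, and 36 genes with diffSplice), and FICD (-0.39 ± 0.07), C1orf21 (-0.39 ± 0.08), CCT2 (0.52 ± 0.11), SGTA (0.32 ± 0.07) and PREX2 (0.52 ± 0.11) had the smallest p.

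Genes called for splicing were more often called at gene level than other genes, by region and for pregnancy. Of the called genes with a gene-level value, 85.0 percent were also called at gene level by region in the pregnant group not in labor and 71.3 percent in labor, against 24.4 and 16.3 percent of the uncalled genes. In the non-pregnant group 27 of 71 were, against 4.97 percent of the uncalled genes. For pregnancy in subcutaneous tissue the shares were 61.9 and 9.10 percent, and in visceral tissue 4 of 5 called genes were, against 1.19 percent. In genes called at gene level, 63.5, 61.7, 66.7 and 74.2 percent of the called probe sets went against their gene in the non-pregnant group, in the pregnant group not in labor, in labor and for pregnancy in subcutaneous tissue, and 9 of 16 probe sets did so for pregnancy in visceral tissue. Without the 5 pairs the splicing counts by region were 1023 in the non-pregnant group and 1507 in labor, and GHITM was not called. Without the subjects of the 3 low-correlation arrays 0 genes were called by region in the non-pregnant group (151 probe sets with all subjects) and 4 for pregnancy in subcutaneous tissue. By region in the non-pregnant group the named probe sets of MSLN, C7, ALDH1A3, KRT18 and ALOX15 differed there by 2.61, -1.03, -0.91, 1.00 and 1.61.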

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

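The list tests of pregnancy by region and labor by region were chosen before the data were examined, and the fits without the 5 pairs at odds with their region label and all tests of the 3 patterns below were chosen after the result was seen.

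A difference between regions brought out 27 list results, by limma's camera on the interaction. For pregnancy by region 15 lists passed, 4 with a positive and 11 with a negative mean interaction. The interaction is the visceral minus the subcutaneous difference, so its sign does not tell in which tissue the change was larger. Mesothelial markers had a mean interaction of 0.6335, immediate early genes 0.2350, interferon response genes 0.1979 and genes of cell proliferation 0.1061. Macrophage markers had the most negative mean at -0.2907, followed by fibroblast and preadipocyte markers at -0.2612, adipocyte identity genes at -0.2318, complement genes at -0.2079 and trophoblast markers at -0.1671. Lipolysis and its control stood at -0.1320, extracellular matrix genes at -0.1210, ribosomal proteins at -0.1184, the heat shock response at -0.1112, RNA splicing factors at -0.0826 and oxidative phosphorylation at -0.0449. The highest of these limma camera adjusted p values was 0.0199, none passed with an estimated correlation (adjusted p = 0.586 to 0.750 with an estimated correlation), and 12 also passed without the 5 pairs. Without the subjects of the 3 low-correlation arrays 9 of the 15 passed in the same direction. There oxidative phosphorylation turned to 0.0396 and passed (limma camera adjusted p = 0.0094), the heat shock response turned to 0.0260 and did not pass, and adipocyte identity, lipolysis, extracellular matrix and RNA splicing factors did not pass either. The number of member genes called in the interaction was 0 in limma over all clusters in each list, where 814 clusters had an unadjusted p under 0.05.

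For labor by region 12 lists passed, 7 with a positive and 5 with a negative mean interaction. Acute phase proteins had a mean interaction of 0.2419, extracellular matrix genes 0.1668, interferon response genes 0.1226, the unfolded protein response 0.1224, skeletal muscle markers 0.1123, RNA splicing factors 0.0894 and oxidative phosphorylation 0.0494. Mesothelial markers stood at -0.5145, lymphatic endothelial markers at -0.2492, erythroid markers at -0.1564, B and plasma cell markers at -0.0963 and cell proliferation at -0.0496. The highest limma camera adjusted p was 0.0476, none passed with an estimated correlation (adjusted p = 0.850 to 0.902 with an estimated correlation), 7 also passed without the 5 pairs and 10 without the subjects of the 3 low-correlation arrays. The unfolded protein response was the exception under both changes at once, with limma camera adjusted p = 0.0184 with an estimated correlation and without the 5 pairs. The mean interaction of the mesothelial markers was -0.00 without the 5 pairs (limma camera adjusted p = 0.735). Lymphatic endothelial markers had regional means of 1.17 in the pregnant group not in labor and 1.16 in labor there. Extracellular matrix genes had -0.29 and -0.30, so these regional differences were nearly equal too.

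The first pattern weighed is the 5 pairs at odds with their region label, which could be exchanged labels or mesothelium carried into the subcutaneous sample. The prediction for exchanged labels was written before its test, and 4 of the 5 pairs had a slope under -0.5 of their own regional differences on the mean regional difference of the other pairs, over 4260 clusters, against 0 of the 46 other pairs. The clusters lay outside the mesothelial and patterning lists. Still, the 5 pairs were chosen for marker levels of the other region, and the 46 other pairs made the mean themselves. The selection thus favoured this outcome, so it does not decide whether labels were exchanged. The prediction for carried mesothelium was written after the levels were seen, and 4 of the 5 visceral arrays were out of place too, which speaks against it. No biological explanation was tested.

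The second pattern is the loss of pregnancy calls in subcutaneous tissue, from 1492 to 125, when the subjects of the 3 low-correlation arrays were left out. Leaving out 3 other non-pregnant subjects gave a median of 4491 calls over 56 sets, with a range of 416 to 9656. Each of these sets kept the 3 low-correlation arrays and raised their share of the group. The number of subjects and the weight of those arrays thus changed together, so this cannot decide whether fewer subjects explain the loss. Quantile normalization of the subcutaneous arrays, with all subjects kept, gave 2368 calls. RMA had already brought the arrays to a common distribution, so this says little about the overall distribution of the values as a cause. Fewer subjects, a tissue property of these subjects and a property of the arrays could each account for it, and the data do not separate them.

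The third pattern is that many splicing calls lay in genes that changed as a whole, and it could come from probe sets that respond less than others to their gene's level. Within groups and regions and without the 5 pairs, the median slope of probe sets on their gene was 0.241 for the 1024 called against their gene, 1.25 for the 635 called with it and 0.918 for the 8794 uncalled probe sets of the same 584 genes. The ratio of the first to the last was 0.262, so weakly responding probe sets may explain many calls of this kind. No biological explanation was tested.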

How the results depend on the processing

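The fits without the 5 pairs, without the subjects of the 3 low-correlation arrays, without both and with array weights were chosen after the result was seen; the other alternatives were fixed before. No named gene turned its direction. Among the lists described here, 4 interactions did: without the 5 pairs, extracellular matrix (-0.0027) and B and plasma cell markers (0.0073) for labor by region, and without the subjects of the low-correlation arrays oxidative phosphorylation (0.0396, limma camera adjusted p = 0.0094) and heat shock (0.0260) for pregnancy by region. Of 2211 values of named genes and lists under the settings fixed before, 252 changed side of the threshold, and of 1548 under the added ones 233 did. Signal over background limits arrays: weak clusters are compressed by RMA, and the fit on bright clusters alone moved 0 of 9 counts by over 1.5 times. A minimum fold and no minimum difference move counts by construction. For the loss of pregnancy calls in subcutaneous tissue without 3 arrays, the tests above decided neither on fewer subjects nor on the array-wide distribution. For all else the cause was not tested.

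In limma, the counts by region in the non-pregnant group, in the pregnant group not in labor and in labor, for pregnancy in subcutaneous and in visceral tissue, for labor in visceral tissue and for pregnancy by region were 700, 4294, 2714, 1492, 159, 0 (1834 at an unadjusted p under 0.05) and 0 (814). With only the compared groups in the fit, 0 were called by region in the non-pregnant group (2969 at an unadjusted p under 0.05) and 79 for pregnancy in visceral tissue. With the subject as a random effect the latter was 349, and with trended and robust variances the former was 429. At least 1.5-fold were 241, 645 and 482 by region and 127 and 42 for pregnancy. Without the 5 pairs they were 2886 in the non-pregnant group, 4563 in labor and 9 for pregnancy by region. Without the subjects of the low-correlation arrays they were 72 in the non-pregnant group, 125 for pregnancy in subcutaneous and 2 in visceral tissue. Without both sets they were 2356, 4792 in labor, 107 and 0 (limma). With array weights they were 3285, 6937 and 4673 by region, 562 and 1772 for pregnancy, 172 for labor in visceral tissue and 9 for pregnancy by region. Centring moved no count by over 1.5 times and no share of higher clusters by over 10 points, but turned the majority, with 306 higher and 253 lower, 1867 and 2602, and 1426 and 1486 by region, and 81 and 82 for pregnancy in visceral tissue. Of the list tests 121 passed, 2 with an estimated correlation, 121 without the 5 pairs and 127 without the subjects of the low-correlation arrays. With an estimated correlation and without the 5 pairs 12 passed.

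The paired fit was compared with no replicate block. The gene counts by region stayed within 1.5 times, at 726, 3912 and 2444, and of the splicing counts the non-pregnant one moved from 81 to 208 genes.

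For splicing, with no minimum difference 2937 genes were called by region in the pregnant group not in labor, 860 in labor and 13 for pregnancy in visceral tissue. With the gene-level values as gene level, 0 were called for labor in subcutaneous tissue in limma. With diffSplice they were 263, 1544 and 762 by region, 1299 and 240 for pregnancy and 17 and 36 for labor, in subcutaneous and visceral tissue. Without the 5 pairs they were 1023 in the non-pregnant group, 1507 in labor, 37 for pregnancy in visceral tissue and 0 for labor in subcutaneous tissue. Without the subjects of the low-correlation arrays they were 0 by region in the non-pregnant group, 4 for pregnancy in subcutaneous and 2 in visceral tissue.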

Other observations

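The lists in the next 2 paragraphs were described and the PRL relations tested after the result was seen, and the limit for the regroupings of the samples was written after the counts were seen.

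Genes of insulin signalling were lower in visceral tissue. Pregnant subjects not in labor had 12 of 20 called lower and 2 higher. Among the lower were the insulin receptor substrate IRS1 at -0.58 ± 0.09, SLC2A4 at -0.66 ± 0.11 and AKT2 at -0.30 ± 0.06 (12 and 2 adjusted over the list alone; limma camera adjusted p = 3.22e-05; adjusted p = 0.229 with an estimated correlation). In labor 6 were called lower and 1 higher, the adaptor SHC1 at 0.28 ± 0.06 (10 and 2 adjusted over the list alone; limma camera adjusted p = 0.0012; adjusted p = 0.403 with an estimated correlation). Non-pregnant subjects had 1 called, with AKT2 lower at -0.28 ± 0.09 (9 lower and 1 higher adjusted over the list alone; limma camera adjusted p = 0.0079; adjusted p = 0.416 with an estimated correlation). The insulin signalling list shares SLC2A4 with the adipocyte identity list and PDE3B with the lipolysis list. Erythroid markers were lower in visceral tissue for 5 of 9 genes in labor, with the membrane gene EPB42 at -0.45 ± 0.10 and the hemoglobin chaperone AHSP at -0.64 ± 0.19 (7 adjusted over the list alone; limma camera adjusted p = 9.83e-04; adjusted p = 0.405 with an estimated correlation). Without labor 5 were lower in the pregnant group and SELENBP1 was higher at 0.29 ± 0.09 (6 and 1 adjusted over the list alone; limma camera adjusted p = 0.0444; adjusted p = 0.593 with an estimated correlation).

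Mural and endothelial genes were lower in visceral tissue of the non-pregnant group and the pregnant group not in labor. Of 13 smooth muscle and pericyte markers 4 were lower in the non-pregnant group. Among these were CSPG4 at -0.62 ± 0.16, MCAM at -0.86 ± 0.23 and NOTCH3 at -0.53 ± 0.14 (8 adjusted over the list alone; limma camera adjusted p = 0.0016; adjusted p = 0.416 with an estimated correlation). In the pregnant group not in labor 7 were lower and 2 higher, with the channel subunit ABCC9 at -1.16 ± 0.15 (8 and 3 adjusted over the list alone; limma camera adjusted p = 0.0392; adjusted p = 0.593 with an estimated correlation). Of 18 endothelial markers 3 were lower in the non-pregnant group, with CLDN5 at -0.44 ± 0.09 (6 adjusted over the list alone; limma camera adjusted p = 9.18e-05; adjusted p = 0.416 with an estimated correlation). Pregnant subjects not in labor had 6 lower, including the lipase anchor GPIHBP1 at -0.37 ± 0.08. The growth factor receptor KDR was higher at 0.78 ± 0.16 (7 and 1 adjusted over the list alone; limma camera adjusted p = 0.0202; adjusted p = 0.594 with an estimated correlation). In labor neither list passed, with limma camera adjusted p = 0.0922 for smooth muscle and pericyte markers and 0.237 for endothelial markers. Without the 5 pairs at odds with their region label both passed in labor, with 8 and 5 lower (limma camera adjusted p = 6.36e-04 and 0.0099; adjusted p = 0.277 and 0.619 with an estimated correlation). In the non-pregnant group 1 smooth muscle marker and 0 endothelial markers were called lower in limma without the subjects of the 3 low-correlation arrays, with list means of -0.34 and -0.35 there. Of 17 fibroblast markers 7 were lower and 3 higher in the pregnant group not in labor. Those lower included CCN5 at -1.36 ± 0.15 and the matrix gene DPT at -0.54 ± 0.10 (7 and 4 adjusted over the list alone; limma camera adjusted p = 0.0443; adjusted p = 0.593 with an estimated correlation).

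PRL, the prolactin gene, had a visceral mean of 7.46 ± 1.71 (SD, n = 25) in the pregnant group not in labor and 7.90 ± 2.10 (SD, n = 15) in labor, against 5.85 ± 1.02 (SD, n = 11) in the non-pregnant group. The pregnancy difference in visceral tissue was 1.60 and did not pass (limma adjusted p = 0.158), and the regional difference was 1.63 in the pregnant group not in labor (limma adjusted p = 0.0021) and 1.67 in labor (limma adjusted p = 0.0259). PRL, its receptor PRLR, DKK1 and IGFBP1 are genes of the decidua, the hormone-changed stroma of the pregnant uterus, and were chosen after their values were seen.

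Decidua-like cells in the sampled tissue could raise PRL, and more mesothelium could do so too. Both were tested over the 40 visceral arrays of the pregnant groups, with 6 measured of 11 decidual markers not looked at before and 100000 permutations, in a family of 8 relations. PRL followed the mean of these markers with a Spearman rho of 0.848 and a Pearson r of 0.871. The permutation p was 1.00e-05, the smallest they can give (r without the 2 most extreme arrays 0.849, Benjamini-Hochberg adjusted p = 2.67e-05). The rho was 0.820 in the 25 arrays of pregnant subjects not in labor and 0.864 in the 15 in labor. Singly, the relaxin receptor RXFP1 had a rho of 0.87 with PRL, IL15 0.63, WNT4 0.46, PGR 0.45, FOXO1 0.08 and BMP2 -0.24, and the mean was not tested without RXFP1. The mesothelial list had a rho of 0.408 and an r of 0.431 (r without 2 arrays 0.359, permutation p = 0.0088, adjusted p = 0.0141), and a rho of 0.288 without the pairs in doubt (permutation p = 0.0879). Its rho was 0.449 in pregnant subjects not in labor (permutation p = 0.0255) and 0.425 in labor (permutation p = 0.117). In labor its r fell from 0.453 to 0.153 without 2 arrays.

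Other regroupings of the same subjects were counted for each result of the limma fits, 100 per result with the real one included. By region in the non-pregnant group 700 clusters were called and the highest other regrouping gave 4070, with 4 as large. That is a share just under 5 in 100, but a fit on that group alone called 0 (limma; 2969 at an unadjusted p under 0.05), so chance is not firmly excluded. A count several times the real one points to a structure of the samples. By region in the pregnant group not in labor the counts were 4294 and 384 at most (1 as large) and in labor 2714 and 2283 (1 as large). Only the real grouping reached either count. For pregnancy the counts were 1492 and 4062 in subcutaneous tissue (2 as large), again with a higher other count that points to a structure of the samples. In visceral tissue they were 159 and 2 (1 as large), so only the real grouping reached the count. Both shares are under 5 in 100. Without the subjects of the 3 low-correlation arrays 125 and 2 clusters were called in these regions, so chance is not firmly excluded. The visceral arrays left out were not themselves low, and whether fewer subjects explain the visceral fall was not tested. For labor the real and the highest other count were 0 and 1 in subcutaneous tissue (100 as large) and 0 and 4968 in visceral tissue (100 as large). The latter again points to a structure of the samples, where limma called none and 1834 clusters had an unadjusted p under 0.05. For the interactions they were 0 and 3 with pregnancy and 0 and 2 with labor (100 as large for each). Every regrouping reaches a real count of 0, so for labor and the interactions in limma these counts decide nothing about chance.

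For splicing, chance was not excluded by region in the non-pregnant group, with 81 genes called, 2062 in the highest other regrouping and 5 as large. By region in the pregnant group not in labor (799 against 1 at most, 1 as large) and in labor (475 against 401, 1 as large) only the real grouping reached the count. For pregnancy the counts were 73 against 661 in subcutaneous tissue (2 as large) and 8 against 0 in visceral tissue in limma (1 as large). Without the subjects of the 3 low-correlation arrays 4 and 2 genes were called in these regions, so chance is not firmly excluded. For labor in subcutaneous tissue the single gene GHITM was matched by other regroupings (1 against 1, 3 as large) and lost its call without the 5 pairs, so chance is not excluded. In visceral tissue the counts were 0 and 1324 (100 as large), which decides nothing. The 2062, 661 and 1324 genes of other regroupings, several times the real counts, point to a structure of the samples.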
